A study of Mus musculus with 2 samples.

How the data were processed

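The 2 libraries came from the sample records as deposited: per the labels, WT held normal duodenum of 3 Lkb1+/+;Myh11-Cre/ERT2 mice and Lkb1_Het held polyps of 3 Lkb1flox/+;Myh11-Cre/ERT2 mice. The series design named polyps against normal duodenum, whereas the source label of both samples read duodenum tissues, so the site of the polyps was taken as not settled by the labels. Cells of the 3 mice were not separable in either library, because all barcodes carried the same suffix. Per the labels, tissue was cut into 0.5 mm3 pieces, digested in 0.2% collagenase at 37 °C for 40 min and passed through a 40 µm strainer.

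Values in the deposited matrices were counts of unique molecular identifiers (UMIs) per gene and barcode, as the file headers state and as whole-number entries showed. The submitters' processing notes gave Cell Ranger 3.0.0 and the mm10 genome, whereas the matrix header gave Cell Ranger 5.0.0. The annotation release behind the gene identifiers was not given in the sources used here. Gene positions were taken from a GENCODE annotation of the same genome by gene identifier. The matrices held 32285 genes, and 38 duplicate symbols were kept as separate rows by identifier.

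Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 25% of UMIs from the 13 mitochondrial genes. Doublet scores came from scrublet as held in scanpy 1.11.5, with an expected rate of 0.8% per 1000 cells. Its automatic thresholds, 0.327 in WT and 0.692 in Lkb1_Het, marked 0 barcodes in either library. The highest scores up to the expected rate were removed instead, 85 barcodes in WT and 573 in Lkb1_Het. This choice was made after the scores had been seen.

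Counts were normalised to 10000 per cell and log-transformed, 2000 variable genes were scaled, and 30 principal components with 15 neighbours fed Leiden clustering at resolution 1.0 over both libraries together, without batch correction, because library and group were the same thing. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin variable and sex-linked genes were kept out of the variable genes. Names came from fixed markers of 29 classes: the class with the highest mean log2 fold (at least 1) over all other cells, with at least 3 markers at 2-fold or more in at least 5% of cells, or failing that a class with 3 markers among the 10 leading genes of the cluster. A plasma-like cluster with Epcam in over 40% of cells was split again at resolution 0.3. Of 29 clusters, 6 stayed unnamed. A cluster with Epcam in over 70% and Ptprc in under 20% of cells but no such class was counted as unnamed epithelium. Clusters with at least 2 of the rRNA-repeat genes AY036118, Gm42418, Gm26917 and Lars2 among their 10 leading genes were set apart as debris, a rule set after the clusters had been seen, whatever other genes led them. Class names below stand for clusters that resemble the class. The software was Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9, with seed 1.

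Gene levels were summed UMIs of a class in a library over all UMIs of that class, in CPM (counts per total of 10⁶), with exact Poisson intervals. Ratios are polyp over normal with exact conditional binomial intervals, and shares carry Clopper-Pearson intervals, all at the 95% level. These intervals cover counting error only: with no replicates, differences between mice, between tissue pieces and between library preparations were not measurable, and no test was run. Where one library held 0 UMIs, the fold is given as at least the value from a floor of 3 UMIs. Where the median gene of a class differed between the libraries by more than 0.1 log2, ratios are given relative to that median.

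The set of classes for gene comparison was fixed before the data were examined as those with at least 100 cells in both libraries, which T cells and plasma cells met. Fibroblasts, enteroendocrine cells, mucous cells (at least 30 cells in both), macrophages (at least 20) and the whole epithelium were added after the cells had been counted. Named genes had at least 50 UMIs, a UMI in at least 10% of the class's cells in the higher library and a class level no lower than the library's own level, and were ranked by the end of the interval nearest 1, which had to lie past 1.5-fold. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, predicted and sex-linked genes were left out of this ranking. The first 10 in either direction are named for epithelium and fibroblasts, and the first 5 for other classes. For each gene list, members with at least 20 UMIs were counted as higher or lower past 1.5-fold with an interval clear of 1, and their median log2 ratio (0.5 UMIs added) was placed among 10000 random lists matched on level. Of 229 list and class pairs, 56 lay above and 45 below the range of random lists (percentiles 2.5 to 97.5). A place outside that range was therefore common and does not by itself single out a list.

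To compare shares of cells with a UMI, cells were thinned to 1000 UMIs and shallower cells were left out. The ratio intervals and the placing among random lists were tested on simulated data, drawn as Poisson counts from the summed WT profile with ratios set for chosen genes. There, 95.8% of intervals over 7106 genes held the true ratio, genes set at 2 had a median ratio of 1.99 with 56.0% called past 1.5-fold, genes set at 0.5 had a median of 0.500 with 26.0% called, and 0.0145% of unchanged genes were called. Of 200 random lists, 4.0% fell outside the central range, and a list of 12 genes set at 2 lay at percentile 100. Genes set at 4 were called in 100% of cases and those set at 0.25 in 90.0%, so moderate differences went uncalled more often than large ones. Filtering, clustering, naming and thinning were not simulated. Poisson counts are what the intervals assume, so their coverage followed from the design. The simulated sums were near those of T-like cells. The rates need not hold for classes with fewer UMIs, such as fibroblast-like (204192 in WT) and macrophage-like cells (86627 in WT).

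Alternatives tried were a strict filter (1000 UMIs, 500 genes, 10% mitochondrial) and no filter, doublets kept, Leiden resolutions of 0.5 and 2.0, 4000 variable genes, clustering of each library alone, naming cell by cell, averaging over cells, scaling to the median gene, removal of 10% free RNA, thinning to 500 UMIs or none, and comparisons without rRNA-repeat clusters, within Cd4-bearing T-like clusters (more Cd4 than Cd8a UMIs, with at least 50 cells of the library or with smaller clusters included), and among fibroblast-like cells at resolution 2.0 with smooth-muscle-like cells apart.

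Barcodes failing the filters, 6698 in WT and 5867 in Lkb1_Het, were not used for the main results. Copy number, velocity, cell-cell signalling scores and immune receptor sequences were not analysed here.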

Results

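Single-cell libraries were compared between polyps of mice with 1 floxed Lkb1 allele and Myh11-Cre/ERT2 (Lkb1_Het) and normal duodenum of mice with Cre and intact Lkb1 (WT), 1 library per group from 3 mice each. Of 9950 barcodes in WT and 14327 in Lkb1_Het, 3252 (32.7%) and 8460 (59.0%) passed the filters, and 3167 and 7887 remained after doublet removal. Barcodes over the mitochondrial limit made up 64.9% of the normal and 39.1% of the polyp library, with median mitochondrial shares of 44.7% and 10.3%. Kept cells had a median of 2431 UMIs and 831 genes in WT and 2284.5 UMIs and 903 genes in Lkb1_Het.

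Stk11 (ENSMUSG00000003068, chromosome 10: 80115803–80130682), which encodes LKB1 and whose germline loss causes Peutz-Jeghers syndrome with hamartomatous polyps, was not lower in the polyp library. Over all kept cells its level was 28.2 CPM (26.0–30.5) in WT and 38.6 CPM (36.9–40.4) in the polyp, a ratio of 1.37 (1.25–1.5045). Normal classes differed in Stk11, for example 8.87 CPM in plasma-like and 46.0 CPM in T-like cells. The ratio over all kept cells can therefore follow the cell mix. In epithelium the ratio was 1.30 (1.17–1.46), but 1.02 with cells averaged instead of summed. In fibroblast-like cells, the class that held nearly all Myh11 UMIs, Stk11 stood at 53.9 against 59.6 CPM, a ratio relative to the class's median gene of 1.27 (0.649–2.70). T-like cells (1.06, 0.790–1.41) and, relative to their median genes, plasma-like (0.938, 0.511–1.73), macrophage-like (1.47, 0.533–5.64) and enteroendocrine-like cells (1.12, 0.730–1.78) had intervals across 1. Before scaling the plasma-like and enteroendocrine-like ratios lay on the other side of 1 (1.26 and 0.849). Of these classes only mucous-like cells were lower (0.660, 0.455–0.991). Counts at the 3′ end of a transcript may lie outside the deleted part, so these levels do not check the deletion. Myh11 (chromosome 16: 14194535–14291372), the smooth-muscle myosin gene behind the Cre driver, stood at 8.60 and 7.90 CPM over all kept cells (ratio 0.919, 0.770–1.10), with 184 of 184 normal and 369 of 399 polyp UMIs in fibroblast-like cells. No cluster carried a smooth-muscle name at the resolution used, and at resolution 2.0 smooth-muscle-like cells (12 and 29) parted from the fibroblast-like ones (32 and 219) and took 179 and 354 of the Myh11 UMIs.

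Epithelial-like cells made up 46.7% (45.6–47.8) of polyp cells and 20.9% (19.5–22.4) of normal cells, a ratio of 2.23 (2.08–2.40), a direction that turned without the cell filter (29.8% and 34.1%, ratio 0.873). Myeloid-like cells, mainly macrophage-, dendritic- and mast-like, reached 8.13% (7.53–8.75) in the polyp against 1.14% (0.797–1.57), stromal-like cells 3.87% (3.45–4.32) against 1.58% (1.17–2.08; under the strict filter a ratio of 1.23, 0.886–1.70), B-like cells 1.86% against 0.316% and blood-endothelial-like cells 0.761% against 0.221%, although endothelial cells turned to a ratio of 0.215 with each library clustered alone. Mast-like cells numbered 135 in the polyp library and 1 in the normal one, and NK- or innate-lymphoid-like cells 144 and 6. These counts moved with the processing: polyp mast-like cells numbered 66 at Leiden resolutions of 0.5 and 2.0 and 53 under the strict filter, and naming cells one by one gave 134 and 13 mast-like (ratio 4.14) and 346 and 69 NK- or innate-lymphoid-like cells (ratio 2.01). T-, NK- and innate-lymphoid-like cells together formed a smaller part of the polyp, 12.2% (11.5–12.9) against 25.5% (24.0–27.1), and so did plasma-like cells, 3.50% (3.10–3.93) against 4.80% (4.08–5.60), but their ratio of 0.729 became 1.16 without the cell filter and 0.969 with cells named one by one. Clusters with rRNA-repeat genes among their leading genes, taken as debris, held 41.2% of normal barcodes (1306) and 22.9% of polyp barcodes (1805). Nearly all of the normal part (1299) was 1 cluster closest to pancreatic acinar cells by its markers. Of these markers, 5 were among its 10 leading genes, beside rRNA-repeat genes and the Paneth gene Defa30. Nearly all of the polyp part (1791) was 1 cluster led by haemoglobin genes and closest to erythroid cells by its markers. Without the cell filter, erythroid-like cells made up 19.2% of polyp and 0.251% of normal barcodes. With the rRNA-repeat clusters removed from the filtered cells, epithelium was 60.6% of polyp and 35.6% of normal cells. In the same order, T-, NK- and innate-lymphoid-like cells were 15.8% and 43.5%, plasma-like cells 4.54% and 8.17%, myeloid-like cells 10.5% and 1.93%, and stromal-like cells 5.01% and 2.69%.

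**Figure D1:**
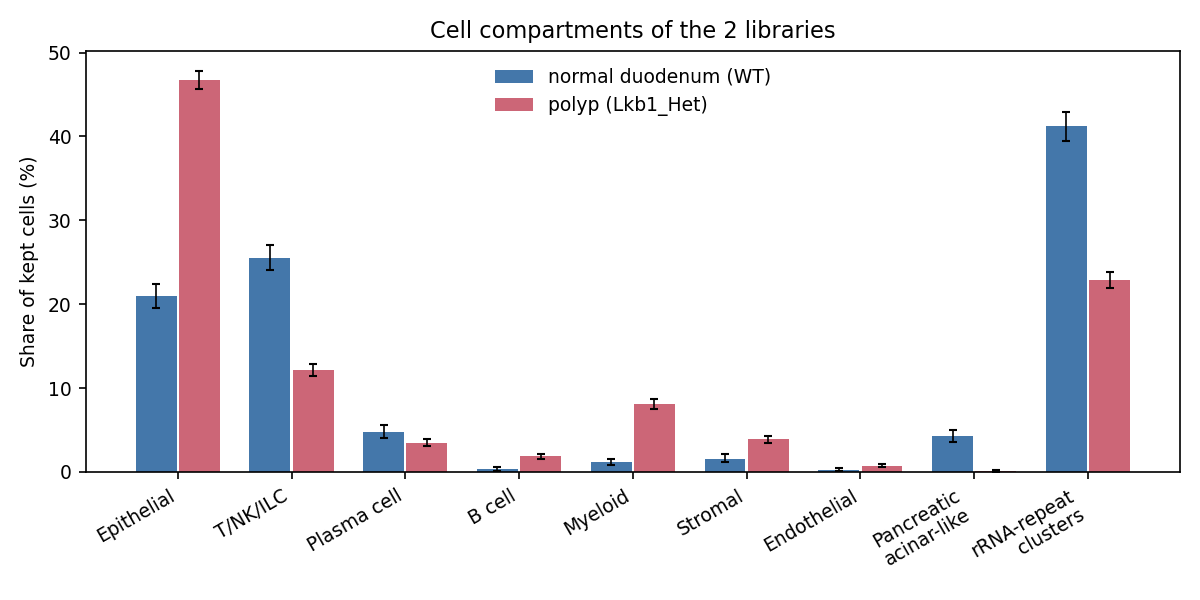
Share of kept cells per compartment in the normal duodenum library (blue) and the polyp library (red), of 3167 and 7887 cells. Bars carry 95% counting intervals. The epithelial and myeloid bars are higher in the polyp library and the T/NK/ILC bar is lower; the epithelial and plasma cell directions turned without the cell filter, and the endothelial one with each library clustered alone. The last pair shows clusters with rRNA-repeat genes among their leading genes, which in the polyp library were nearly all 1 cluster led by haemoglobin genes. In the normal library they were nearly all 1 cluster closest to pancreatic acinar cells by its markers.

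The epithelium of the polyp library lacked the absorptive programme of the normal library and carried gastric genes. Fabp1, the fatty acid binding protein of enterocytes, stood at 9188 CPM in normal and 4.70 CPM in polyp epithelium, 1955-fold lower (1698–2264). The apolipoprotein genes Apoa4 (767 against 0.365 CPM) and Apoc3 (418 against 0.317 CPM) and the disaccharidase gene Sis (540 against 0.243 CPM, 2216-fold, 1204–4623) lay as far apart. Gast, which encodes gastrin and sits on chromosome 11 (100334407–100336996), had 0 UMIs in normal and 1410 CPM in polyp epithelium, and Cblif, the gastric intrinsic factor gene, 0 and 157 CPM, at least 686-fold higher. Chil4, a chitinase-like gene, went with them at 0 and 961 CPM, at least 4193-fold.

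The other genes ranked highest in polyp epithelium were Mug1 (0.458 and 349 CPM, 761-fold, 349–2073), Khdc1a (121 CPM, against 1 UMI in WT, 1587-fold, 285–62701), Serpina3n (at least 242-fold), Mup18 (at least 238-fold), the mucosal chemokine gene Cxcl17 (0.764 and 190 CPM, 248-fold, 135–518), the proton pump subunit gene Atp6v0d2 (238-fold, 115–592) and the complement gene C4b (156-fold, 96.1–273). Lower in the polyp were also Arg2 (682 and 0.682 CPM, 1000-fold, 691–1506), the aryl hydrocarbon receptor target Cyp1a1 (54.8 CPM and 0 UMIs), Leap2 (107 CPM, against 2 UMIs in the polyp), Sult6b2 (799-fold, 545–1225), Adh6a (666-fold, 502–904) and Ugt2b5 (62.6 CPM, against 1 UMI in the polyp). Regional transcription factor genes, chosen after the values were seen, split the same way: the gastric and oesophageal gene Sox2 stood at 0.458 in normal and 22.2 CPM in polyp epithelium (48.4-fold, 22.1–132), whereas the intestinal genes Cdx2 (59.7 and 2.48 CPM) and Cdx1 (58.1 and 0.317 CPM) were 24.0-fold and 184-fold lower.

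**Figure D2:**
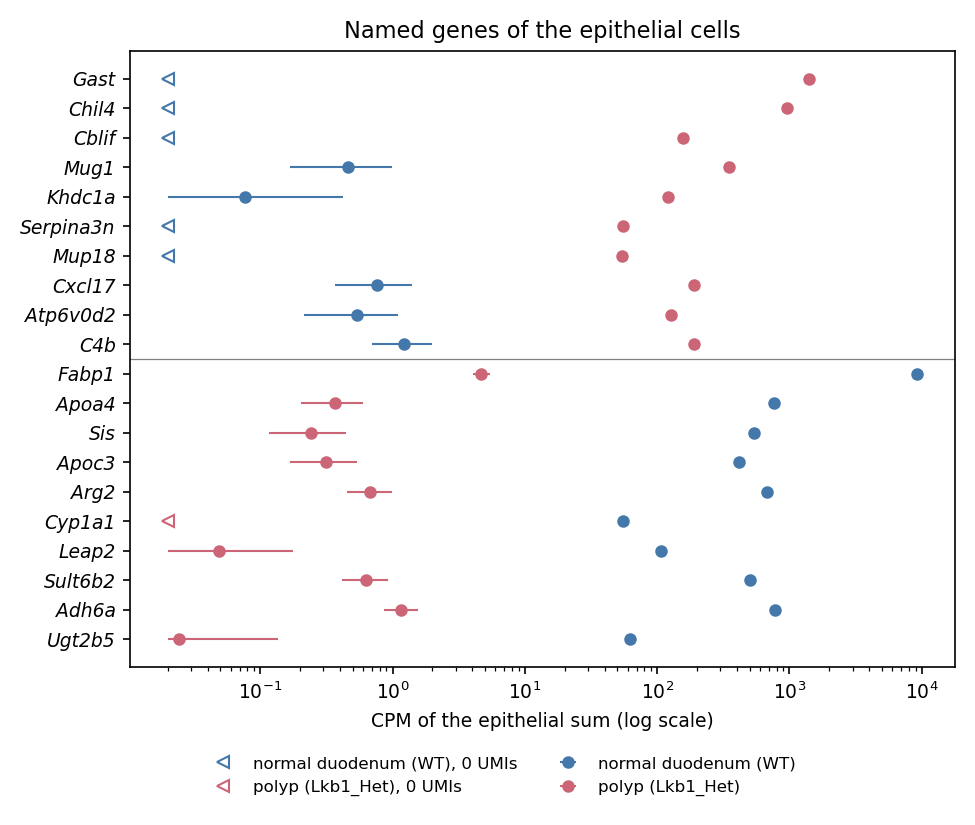
Levels of the 20 named genes of the epithelium on a log scale, in CPM of the epithelial sum, with 95% counting intervals. Blue is the normal library and red the polyp library. The upper 10 genes are higher and the lower 10 are lower in the polyp. Open triangles mark genes with 0 UMIs in that library.

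Absorption and antigen presentation lists were lower in the summed polyp epithelium. All 17 measured members of the lipid absorption list were lower, among them Apoa1 (446-fold) and Fabp2 (71.5-fold), with a median log2 ratio of −6.16, where random lists lay between −0.56 and 0.24. Of 16 brush border genes 15 were lower (median −6.14), including Slc2a2 (760-fold) and the alkaline phosphatase gene Alpi (27.6-fold), and Ezr was near 1 (0.959). Of 8 iron handling genes 5 were lower (median −1.84), among them Slc40a1 and Slc11a2. All 7 MHC class II genes were lower (median −4.05, random lists −0.81 to 0.60), led by the invariant chain gene Cd74 at 852 and 21.7 CPM (39.3-fold, 36.7–42.1), although within enteroendocrine-like cells 2 of 4 were higher and 1 lower (median relative to the class 1.05), and 9 of 10 MHC class I genes followed (median −2.18), such as B2m (1034 and 194 CPM) and Psmb8 (469 and 16.8 CPM). Interferon response genes were lower in 11 of 15 cases (median −2.34), for example Isg15 (210 and 20.8 CPM) and Bst2 (198 and 36.7 CPM).

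Gastric and Brunner-gland mucus genes and injury-linked genes were higher instead. Of 15 mucus genes 9 were higher and 5 lower (median 2.11): Tff1, a gastric surface trefoil gene, stood at 2649 and 38472 CPM, Tff2 stood at 11619 and 70507 CPM, and Gkn1 (13.2-fold), Muc5ac (12.9-fold) and Muc6 (3.04-fold) were higher too. Few normal cells made these normal levels: 8 gastric-surface-like cells held 34389 of 34676 normal Tff1 UMIs, and 24 Brunner-gland-like cells 142322 of 152070 normal Tff2 UMIs. The intestinal goblet genes Tff3 (47.5-fold) and Muc2 (41.1-fold) were lower. The regenerative and fetal-like list had 10 of 13 members higher (median 2.11, random lists −0.62 to 0.33), with Clu at 168 and 6259 CPM, Spp1 at 30.4 and 970 CPM and Anxa1 at 8.10 and 254 CPM. Interleukin-6 and JAK-STAT3 genes were higher in 10 of 16 cases (median 1.56), including Socs3 (24.9 and 74.6 CPM) and Stat3 (23.2 and 70.3 CPM), and sterol and lipid synthesis genes such as Scd1 and Fasn in 10 of 18 (median 0.65). Antimicrobial genes parted: 9 of 14, such as the Paneth gene Lyz1 (24.8-fold) and Defa30 (21.3-fold), were lower, while Reg3b (343 and 4075 CPM) and Reg3g (327 and 1526 CPM) were higher. Nuclear oxidative phosphorylation genes were lower in 17 of 25 cases (median −0.71), glycolysis genes in 10 of 16 (median −0.98) and proliferation genes in 9 of 20 (median −0.48). The Wnt target list was split, with Cd44 (8.70-fold) and Sox9 (3.35-fold) higher, Axin2 3.27-fold lower and the stem cell gene Lgr5 near 1 (1.28, 0.898–1.87). LKB1 and AMPK kinase genes (6 higher, 2 lower of 19, median 0.28) and CRTC and CREB targets (4 higher, 1 lower of 14, median 0.04) lay within the range of random lists.

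The epithelial clusters behind these sums hardly overlapped. Normal epithelium was crypt-like (258 cells), enterocyte-like (202), goblet-like (72) and Paneth-like (21), types with 19, 2, 3 and 1 cells in the polyp library. With cells named one by one, enterocyte-like (608 and 17) and Paneth-like cells (209 and 28) stayed scarcer in the polyp, but crypt-like (147 and 569, share ratio 1.55, 1.30–1.85) and goblet-like cells (91 and 449, 1.98, 1.59–2.47) did not. Polyp epithelium lay mostly in unnamed clusters of 1216, 589, 448 and 404 cells, which held 11, 2, 0 and 20 normal cells and can stand for that library as much as for a type. By cluster, only mucous-like (32 and 653 cells) and enteroendocrine-like cells (45 and 350) could be compared by type. The mucous-like class joined a Brunner-gland-like cluster (24 and 229 cells; Muc6 15097 and 12038 CPM) and a gastric-surface-like one (8 and 424 cells).

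Enteroendocrine-like cells, in 1 cluster, made different hormones in the libraries. Ratios are relative to their median gene, which lay at −0.40 log2. Gast had 0 UMIs in normal and 27743 CPM in polyp cells, at least 3361-fold higher, and the pancreatic polypeptide gene Ppy 0 and 3114 CPM, at least 377-fold. Pyy was 44.6-fold higher (39.1–51.1; 802 and 27118 CPM), and the gastric genes Pgc (57.5-fold, 40.0–85.9) and Cldn18 (at least 41.0-fold) were higher as well. The secretin gene Sct, a duodenal hormone, stood at 7591 and 20.3 CPM, 284-fold lower (208–399), with Reg4 (320-fold, 251–414), Afp (1234-fold, 420.5–6000; 3 UMIs in the polyp), the intestinal cadherin gene Cdh17 (at least 170.1-fold) and Tpbg (163-fold, 77.7–410) also lower. After thinning to 1000 UMIs, 39.7% (34.3–45.4) of polyp enteroendocrine-like cells held a Gast UMI against 0 of 39 normal ones (limit 7.69%), with 33 and 6 shallower cells left out and class medians of 4942.5 and 4812 UMIs. In polyp T-like cells, which should lack Gast, 9.63% held one, and without thinning the polyp shares were 51.4% and 18.8%.

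Mucous-like cells differed less. Their mix was unlike, as Brunner-gland-like cells were 24 of 32 in WT but 229 of 653 in the polyp. The Brunner-gland-like and gastric-surface-like clusters were summed, so the differences below can come from that mix. Wfdc18 was among the leading genes of the Brunner-gland-like cluster. Spink4 stood at 136 and 1836 CPM (13.5-fold higher, 11.1–16.6), with Ly6d (11.97-fold), Gstp1 (9.80-fold), Fbln1 (at least 7.05-fold) and the hedgehog ligand gene Shh (11.9-fold, 4.05–58.0; 3 UMIs in WT) also higher. Ceacam10 (9.23-fold), Fcgbp (6.57-fold), Wfdc18 (5.96-fold), Thbs1 (5.88-fold) and Edn2 (5.19-fold) were lower in the polyp. Dissociation-linked immediate-early and heat shock genes were lower in 13 of 19 cases (median −0.93), Wnt targets in 6 of 11 (median −1.30), and sterol synthesis genes higher in 7 of 18 (median 0.55). EGF family ligands were higher in 3 of 4 cases (median 1.32). MHC class II genes were too low in normal mucous-like cells (Cd74 at 23.6 CPM from 17 UMIs) for a fall to show.

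T-like cells of the normal duodenum were cytotoxic and intraepithelial in kind, and those of the polyp were not. Gzma (ENSMUSG00000023132), a granzyme gene of killer lymphocytes, stood at 19700 CPM in normal and 41.7 CPM in polyp T-like cells, 472-fold lower (375–604), Gzmb at 3401 and 52.7 CPM (64.5-fold, 52.5–80.2), and Cd7 at 1753 and 32.4 CPM (54.1-fold, 41.6–71.7). Dapk2 (51.1-fold, 27.7–107) and Mei1 (55.7 CPM and 0 UMIs, at least 32.0-fold) followed. Higher in the polyp were the chemokine receptor gene Cxcr4 (3.87 and 177 CPM, 45.8-fold, 24.6–96.6), Marcksl1 (20.8-fold, 12.3–37.8), Tnfsf11, which encodes RANKL (3.48 and 72.4 CPM, 20.8-fold, 10.6–46.6), Tmem64 (16.4-fold, 10.1–28.2) and S100a4 (63.0 and 809 CPM, 12.8-fold, 10.9–15.2). Within Cd4-bearing clusters of at least 50 cells, 68 normal cells against all 817 polyp T-like cells, these differences were smaller. Cd7 (ratio 0.574, 0.304–1.18), Dapk2 (0.410, 0.105–2.32), Mei1 (1 and 0 UMIs) and Gzmb (1.12, 0.581–2.41) had intervals across 1, and Tnfsf11 was 3.84-fold and Tmem64 2.02-fold higher. Gzma stayed lower (0.143, 0.1002–0.204), from a normal level of 292 CPM (62 UMIs). Normal plasma-like cells, which should lack granzymes, held Gzma and Gzmb at 63.6 CPM together. Part of the Gzma level in normal Cd4-bearing cells can thus be free RNA. With 14 normal cells of the polyp's cluster included, Gzmb was lower too (0.242, 0.172–0.343). These 14 cells counted as Cd4-bearing on 2 Cd4 UMIs against 1 Cd8a UMI. They held 47 of the then 57 normal Gzmb UMIs, so this difference rested on them.

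Lists for T-cell function split along the same line. Of 11 cytotoxicity genes 10 were lower (median −2.66, random lists −0.53 to 0.47), including Ccl5 (9.42-fold), Nkg7 (8.25-fold) and Prf1 (4.28-fold), and only Eomes was higher (7.75-fold). Of 12 regulatory and checkpoint genes 10 were higher (median 2.06, random lists −0.49 to 0.51): Foxp3, the regulator of suppressive T cells, at 2.71 and 38.2 CPM (14.1-fold, 6.49–36.5), Il2ra (12.7-fold, 7.30–24.0), Icos and Tnfrsf4, with Lag3 lower. Helper cytokines and regulators were higher in 6 of 9 cases (median 1.35), with Il17a at 38.7 and 288 CPM (7.44-fold, 5.99–9.32), Il22 (5.10-fold) and Gata3 (4.18-fold), and Ifng 3.30-fold lower (2.91–3.76; 565 and 171 CPM). CRTC and CREB targets, genes that LKB1-dependent kinases restrain, were higher in 8 of 13 cases (median 0.995, random lists −0.45 to 0.43), among them Crem (6.90-fold, 5.44–8.85), Sik1 and Areg. Interleukin-6 and JAK-STAT3 genes (7 of 10 higher, median 1.08; Stat3 2.45-fold), Wnt targets (6 of 9, median 1.83; Tcf7 3.58-fold and Lef1 3.61-fold), proliferation genes (10 of 18, median 1.07) and inflammatory cytokines (7 of 8, median 1.93) leaned the same way. The Cd4-bearing clusters alone set 68 normal cells against all 817 polyp T-like cells, a mixed cluster that also held Trdc, Cd8a and Cd8b1. In that comparison the cytotoxicity (median 0.11) and helper lists (−0.70) turned, also with 14 normal cells of the polyp's cluster counted in (0.28 and −0.40). Il17a was lower in the polyp there (ratio 0.617, 0.496–0.774). The inflammatory cytokine list turned only without those cells (−0.18, against 0.05 with them), and the regulatory list only with them (−0.20). CRTC and CREB targets (5 higher and 2 lower of 13, median 0.16), interleukin-6 and JAK-STAT3 genes (2 of 9 higher, median 0.51) and Wnt targets (2 of 8 higher, median 0.91) differed less there than in the whole class. Interferon response genes did not lean (6 higher, 2 lower of 15, median 0.01).

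The T-like class consisted of different clusters in each library. Normal T-like cells lay in clusters 10 (485 cells), 2 (236), 11 (68) and 9 (14), and all 817 polyp T-like cells in cluster 9. The number of polyp T-like cells depended on the naming. With cells named one by one, 719 normal and 272 polyp cells were T-like (share ratio 0.152, 0.133–0.174). NK- or innate-lymphoid-like cells then numbered 69 and 346. With 4000 variable genes, 797 normal and 0 polyp cells kept the T cell name, although 957 polyp cells were counted as T-, NK- or innate-lymphoid-like. Cluster 2 carried Trdc (598 CPM), Tcrg-C1 (856 CPM) and Cd8a (1131 CPM) with little Cd8b1 (6.04 CPM), as gamma-delta intraepithelial lymphocytes do, and cluster 10 carried both Cd8a (698 CPM) and Cd8b1 (561 CPM) with little Trdc. Cluster 11, small and normal only, carried Cd4 (108 CPM) with 0 UMIs of Trdc, Cd8a and Cd8b1. The polyp cluster was a mixture, with Trdc (80.5 CPM), Cd4 (74.1 CPM), Tcrg-C1 (45.8 CPM), Cd8b1 (31.3 CPM) and Cd8a (24.3 CPM).

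Thinned to 1000 UMIs, 46.1% (42.6–49.7) of normal and 2.41% (1.43–3.78) of polyp T-like cells held a Cd8a UMI, 65.1% (61.7–68.5) and 3.34% (2.17–4.89) a Gzmb UMI and 11.1% (8.996–13.5) and 5.08% (3.62–6.91) a Trdc UMI. Cd4 ran the other way, 1.66% (0.887–2.82) and 7.22% (5.47–9.31), with Il17a (1.02% and 8.42%) and Foxp3 (0.128% and 3.34%). Here 20 of the normal and 69 of the polyp cells were too shallow (class medians 3175 and 1936 UMIs). Plasma-like cells, which should lack these genes, held at most 1 positive cell of 148 in WT (0.676%) and 0 of 275 in the polyp (limit 1.09%). Without thinning the shares were 73.8% and 4.16% for Cd8a, 73.8% and 5.02% for Gzmb, 17.6% and 6.12% for Trdc, 4.73% and 12.9% for Cd4, 1.62% and 10.5% for Il17a, and 0.498% and 5.75% for Foxp3.

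Fibroblast-like cells (44 and 304, in 1 cluster) carried a foregut regional gene in the polyp only. Their median gene lay at −0.19 log2, and ratios are relative to it. Barx1, a homeobox gene of stomach mesenchyme (chromosome 13: 48662998–48666507), had 0 UMIs in normal and 152 CPM in polyp cells, at least 11.8-fold higher, and Isl1 (0 and 69.3 CPM, at least 5.40-fold) and Pitx1 (0 and 64.4 CPM, at least 5.02-fold), also developmental transcription factor genes, followed. The Wnt antagonist gene Sfrp1 stood at 426 and 1771 CPM (4.76-fold, 3.83–5.98) and the wound matrix gene Tnc at 24.5 and 232 CPM (10.9-fold, 4.57–33.8). Ebf1 (774 and 90.0 CPM, 7.51-fold, 5.67–10.0), Pcolce2 (10.9-fold, 6.34–19.8), Adamts5 (9.47-fold, 5.96–15.5) and Cd248 (8.30-fold) led the lower genes. Also higher were Col6a5 (13.3-fold, 4.45–65.1; 3 UMIs in WT), Ctsc (at least 4.83-fold), Hmox1 (17.3-fold, 2.997–696; 1 UMI in WT), the EGF receptor ligand gene Ereg (7.96-fold, 2.63–39.4; 3 UMIs in WT) and Cxcl10 (4.41-fold, 2.62–8.02), and also lower Scara5 (8.21-fold), Adm (5.86-fold), Cpe (5.41-fold, but a ratio of 0.747 with smooth-muscle-like cells apart), Igfbp6 (5.25-fold), Fbln2 (5.14-fold) and Inmt (5.03-fold). Thinned to 1000 UMIs, 10.6% (6.84–15.5) of polyp and 0 of 39 normal fibroblast-like cells held a Barx1 UMI (87 and 5 left out, class medians 2016 and 4777 UMIs, 17.1% without thinning), against 0 of 748 polyp T-like cells (limit 0.401%).

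Ligand genes for the EGF receptor family were higher in polyp fibroblast-like cells, and contractile genes were lower only while smooth-muscle-like cells were counted among them. In the whole class 9 of 18 contractile genes were lower (median −0.63, or −0.83 before scaling, where random lists lay between −0.46 and 0.18), among them Tpm2 (2.43-fold), Acta2 (1.81-fold) and Myh11, at 901 and 449 CPM. At resolution 2.0, with the 12 and 29 smooth-muscle-like cells apart, 3 of 13 contractile genes were higher in fibroblast-like cells (median 0.38), and within smooth-muscle-like cells 3 of 18 were higher and 2 lower (median −0.13), with Myh11 at 3061 and 2512 CPM (relative ratio 0.952, 0.793–1.15). Myh11 UMIs were found in 25.6% (13.04–42.1) and 12.9% (8.75–18.1) of thinned cells, and in 31.8% and 12.5% of all cells. Hbegf (5.00-fold), Nrg1 and Ereg were the higher 3 of 4 EGF family ligands (median 2.32; 2.15 at resolution 2.0). Bmp4 (3.98-fold), Bmp2 (2.94-fold) and Bmp5 (2.64-fold) were higher and Gdf10 lower among 7 BMP ligands, whose median was low (−0.59, or −0.79 before scaling, where random lists lay between −0.64 and 0.37). CRTC and CREB targets were higher in 5 of 11 cases (median 1.003), TGF-beta pathway genes in 5 of 14 (median 0.73; Thbs1 and Smad7), collagens and matrix genes in 7 of 19 (2 lower, median 0.42; Postn 3.35-fold and Col3a1 2.02-fold) and chemokines in 6 of 14 (3 lower, median 0.81). Basement membrane genes such as Nid1 were lower in 5 of 10 cases and higher in 1 (median −0.87). The interleukin-6 list did not lean (median −0.07), although Il11 had 0 UMIs in normal and 38.9 CPM in polyp cells, and Ptgs2, which encodes cyclo-oxygenase-2, was 2.29-fold higher (1.55–3.53).

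More IgM and IgG1 heavy chain RNA was counted in plasma-like cells of the polyp, while the IgA gene Igha, a leading gene of the plasma-like clusters, differed little. Ratios are relative to their median gene at 0.43 log2. Ighm stood at 12.3 CPM in normal cells and was 28.7-fold higher in the polyp, Ighg1 was 14.1-fold higher, Ighg2c 20.9-fold lower and Igha near 1 (0.775). Ighm was also a leading gene of B-like cells, 147 in the polyp and 10 in the normal library, so free RNA can be part of its level. Pde4b (12.9-fold, 5.31–41.0), Dusp4 (8.02-fold, 4.85–14.1), Ctla4 (11.6 and 89.5 CPM, 5.75-fold, 3.91–8.75), Ripor2 (5.49-fold) and the costimulatory receptor gene Cd28 (4.07-fold, 2.83–6.01) were higher. Ly6k (20.7-fold, 15.02–29.2), Klf2 (4.63-fold), Fos (4.36-fold, 4.16–4.58), Jun (4.29-fold) and Ier2 (4.18-fold) were lower, and 11 of 19 dissociation-linked immediate-early and heat shock genes with them (median −0.79). CRTC and CREB targets such as Nfil3 (3.34-fold) and Areg (3.38-fold) were higher in 7 of 10 cases (median 1.01), interleukin-6 and JAK-STAT3 genes in 4 of 8 (median 0.91), and unfolded protein response genes lower in 5 of 12 (median −0.54). Areg is also on the regenerative and fetal-like epithelial list, and epithelial transcripts were counted in these cells (Tff1, Tff2, Gkn1 and Gkn2 at 1.31% of polyp UMIs). Normal plasma-like cells lay in cluster 5 (146 of 152), and polyp ones in clusters 28 (191) and 27 (84).

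Macrophage-like cells (22 and 337, in 1 cluster) held less MHC class II RNA in the polyp. Relative to a median gene at −0.22 log2, 6 of 7 MHC class II genes were lower (median −0.68), Cd74 by 1.85-fold, and 3 of 8 MHC class I genes, including Psmb8 (3.13-fold). Cbr2 (4.50-fold), Acp5 (3.94-fold), Cd48 (3.92-fold) and Klf2 (2.46-fold) were lower too. Thbs1 (16.2-fold, 4.44–135; 2 UMIs in WT), Hilpda (22.4-fold, 3.96–889.5; 1 UMI in WT), Gadd45b (14.3-fold, 3.90–119; 2 UMIs in WT) and Hspb1 (7.25-fold) were higher, and matrix protease genes were higher in 3 of 6 cases (median 1.81). Chil4, at least 40.1-fold higher, was also a gene of polyp epithelium.

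**Figure D3:**
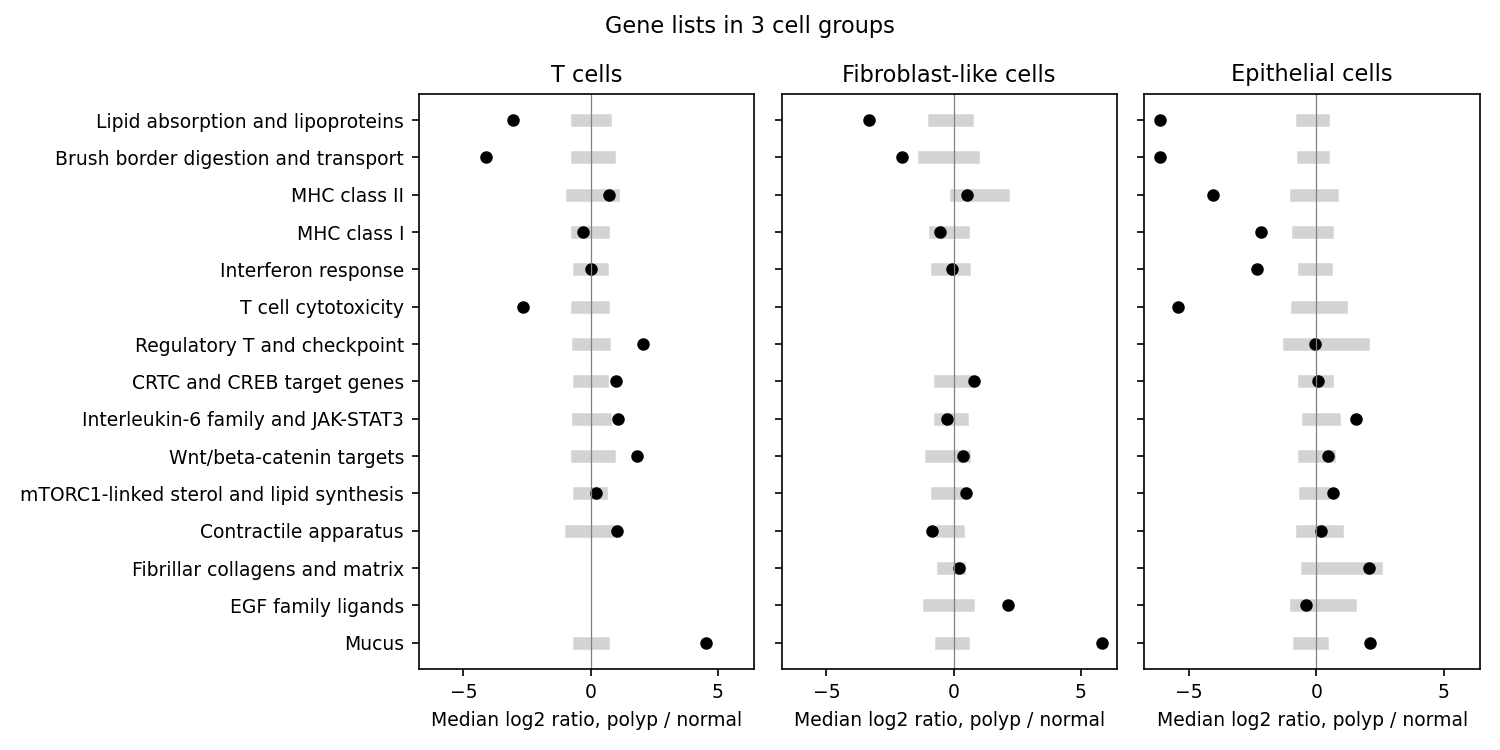
Median log2 ratio, polyp over normal, of gene lists (points) in T-like, fibroblast-like and epithelial-like cells, before scaling to the median gene. Grey bars span the medians of random lists matched on level. Cytotoxicity lies low and regulatory genes high in T-like cells, directions that turned within Cd4-bearing clusters (regulatory genes with small clusters included), and absorption and MHC class II lists lie low in epithelium. Contractile genes lie low in fibroblast-like cells, which turned with smooth-muscle-like cells apart. Mucus, absorption and brush border points of the T-like and fibroblast-like panels are from epithelial genes.

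Epithelial transcripts were also counted in classes that should lack them. Tff1, Tff2, Gkn1 and Gkn2 together made up 14.1% of polyp epithelial UMIs, and still 4.93% in fibroblast-like, 3.47% in T-like and 1.31% in plasma-like cells, against 1.72%, 0.0578%, 0.107% and 0.0290% in WT. In T-like cells, mucus genes (median 4.52) and regenerative genes such as Clu (8.89 and 998 CPM) were higher, and lipid absorption (median −3.04) and brush border genes (median −4.11) lower, as in epithelium. Mucus genes were higher in fibroblast-like cells as well (median 6.02). Sox9, counted among Wnt targets of T-like cells (10.1-fold), stood at 271 CPM in polyp epithelium and 51.0 CPM in polyp T-like cells. The cytotoxicity list in epithelium (7 of 7 lower, median −5.45) went the way of the T-like cells.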

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

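The tests of Barx1 and of the presence of Nkx2-3 in fibroblast-like cells, of free RNA by Tff1 and Muc6, of MHC class II genes within mucous-like cells and of Ifng were chosen after the results they bear on had been seen.

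Signals outside the cells used for the main results drew attention in 3 places. Barcodes that failed the cell filter (5867 in the polyp and 6698 in the normal library) held Tff1 at 13352 CPM in the polyp against 149.9 CPM in WT, and Gast at 163 CPM against 0.289 CPM. In clusters with rRNA-repeat genes among their leading genes (1805 and 1306 barcodes), the haemoglobin gene Hba-a1 stood at 16009 CPM in the polyp and 10092 CPM in WT. Haemoglobin genes led the cluster that held 1791 of these polyp barcodes, so this level describes the cluster itself.

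Polyp epithelium carried gastric genes (Gast, Cblif, Tff1, Sox2) and held little of the intestinal Cdx1, Cdx2 and Fabp1. Free RNA alone would give polyp mucous clusters alike ratios of Tff1 to Muc6 UMIs, and these differed 3554-fold (1146 against 0.322). Tff1 and Muc6 were among the leading genes of these clusters, so a gap was built in by the clustering and cannot decide the question. The unnamed polyp clusters were not part of it. In the polyp, Tff1, Tff2, Gkn1 and Gkn2 made up 14.1% of epithelial UMIs, against 4.93% in fibroblast-like, 3.47% in T-like and 1.31% in plasma-like cells. An identity limited to the epithelium of a duodenal site would leave the stroma without Barx1, which polyp fibroblast-like cells held at 152 CPM, and a stroma without the intestinal gene Nkx2-3 would not hold it at 51.1 CPM (36.8–69.0; 0 UMIs in polyp T-like cells). Tissue of stomach or pyloric position is consistent with Barx1 at least 10.3-fold over WT before scaling, but stomach alone would not account for Cdx2 in Brunner-gland-like (17.4 in WT, 15.1 CPM in the polyp) and crypt-like polyp cells (78.7 CPM from 5 UMIs), and a change of identity in both compartments was not tested. A reduced Nkx2-3 level cannot be told apart from no difference, since the ratio of 0.613 (0.342–1.15) had an interval across 1 with few UMIs, and site, genotype and library preparation were confounded throughout.

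Granzyme and Cd8a RNA was nearly absent from polyp T-like cells. Free RNA in the normal library would reach its plasma-like cells too, but Gzma and Gzmb stood 363-fold higher in normal T-like than in normal plasma-like cells. Loss of cytotoxic polyp cells to the filter would leave their RNA among the left-out barcodes, where the granzyme to Cd3 ratio reached only 8.59% of that in WT (0.398 against 4.64). Left-out polyp barcodes still held Gzma and Gzmb at 4.04 CPM each, against 1.92 and 2.44 CPM over kept polyp cells. In WT, Gzma was lower among left-out barcodes than over kept cells (194 against 2546 CPM). Some loss in the polyp was thus not excluded. A different mix of subsets was examined with Cd4-bearing clusters alone (68 and 817 cells). There the median size of the differences was 58.6% of that in the whole class (log2 0.96 against 1.63). It was 57.7% with 14 normal cells of the polyp's cluster included. The 1122 genes behind these values were not screened for free RNA. Mucus (median 3.78) and lipid absorption genes (median −1.84) still differed within the Cd4-bearing clusters. The percentages thus cannot tell how much of the T-cell difference a mix of subsets accounts for. A different mix of subsets cannot be told apart from a change within subsets. The polyp library gave a single, mixed T-like cluster (Trdc 80.5 and Cd4 74.1 CPM), to which only 68 or 82 normal cells compare. That cluster had 10 T-cell markers enriched, but 0 among its 10 leading genes. How many polyp cells were T-like rather than NK- or innate-lymphoid-like depended on the naming, so their part in the pattern was not settled either.

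MHC class II genes were lower in polyp epithelium. Free immune RNA in the normal library would give epithelial and T-like cells alike levels of Cd74, but Cd74 stood 18.7-fold higher in normal enterocyte- and crypt-like cells than in normal T-like cells (1025 against 54.9 CPM). Different epithelial types in each library cannot be told apart from a fall within types: mucous-like cells had a median log2 ratio of −0.0669, but their normal cells held too little Cd74 (23.6 CPM) for a fall to show, and in enteroendocrine-like cells 2 of 4 genes were higher and 1 lower (relative median 1.05). Less interferon-gamma from T cells is consistent with the values, as Ifng in polyp T-like cells was 0.303 of its normal level (0.266–0.343). Both stayed open, and neither Ifng protein nor its source per mouse was measured here.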

How the results depend on the processing

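Comparing only Cd4-bearing clusters, setting smooth-muscle-like cells apart, leaving out clusters with rRNA-repeat genes among their leading genes, and every alternative for the classes added after cell counting were chosen after the data had been seen. No paired analysis was possible because each group had 1 library and its cells carried no mouse label.

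Keeping doublets, Leiden resolutions of 0.5 and 2.0 and 4000 variable genes left the 7 class share ratios within their reported intervals. With 4000 variable genes, however, 0 polyp cells (797 normal) kept the T cell name, although 957 were counted as T/NK/ILC. The strict filter gave 2.66 for epithelial, 0.337 for T/NK/ILC, 5.09 for myeloid and 1.23 for stromal cells. Without a cell filter the ratios were 0.873 for epithelial and 1.16 for plasma cells, both reversed, and 0.843 for T/NK/ILC, 10.8 for myeloid, 4.19 for stromal and 6.71 for endothelial cells. With each library clustered alone they were 1.75 (epithelial), 4.61 (myeloid), 1.61 (stromal) and 0.215 (endothelial, reversed from 3.44), and B cells had no ratio, as 0 normal cells were named. With cells named one by one they were 1.24 (epithelial), 0.315 (T/NK/ILC), 0.969 (plasma), 2.59 (myeloid), 4.62 (stromal), 3.003 (B cells) and 6.49 (endothelial). Without rRNA-repeat clusters they were 1.70 (epithelial), 0.363 (T/NK/ILC) and 0.556 (plasma). For the filter and naming settings the cause was not tested.

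Of gene lists, the median for T cell cytotoxicity in T cells went to 0.11 and that for brush border genes to 0.27, both reversed, when only Cd4-bearing clusters were compared. By construction this leaves out the Cd8a-bearing normal clusters but none of the polyp T-like cells. Gzmb, at a ratio of 1.07 (0.5 UMIs added), reversed too, but it stayed lower in the polyp with small clusters included (0.242, 0.172–0.343). The 14 normal cells then added held 47 of the 57 normal Gzmb UMIs. With small clusters included the medians were 0.28 (cytotoxicity), 0.57 (brush border) and −0.20 (regulatory genes), all reversed. Other lists changed sign as well, among them T helper (−0.70 from 1.35), inflammatory cytokine (−0.18, but 0.05 with small clusters included, from 1.93), chemokine (−0.17 from 2.05) and antimicrobial genes (2.05 from −5.73). Those named here are not counted as reversed below, because the interval of their members' median in the whole class included 0. With smooth-muscle-like cells apart, contractile genes in fibroblasts went to 0.21 from −0.83, reversed. Scaling to the median gene took oxidative phosphorylation in plasma cells to −0.00654, reversed from 0.42. Removing 10% free RNA took MHC class I in mucous cells to 0.0168 and collagens in epithelium to −1.63, both reversed, EGF family ligands in fibroblasts to 2.93 and MHC class II in epithelium to −12.994, where polyp sums reached 0 after subtraction. Stk11 in epithelium went to 1.02 with cells averaged instead of summed; the cause was not tested. Removal of free RNA over all kept cells was not run for Stk11, because it subtracts the library's own profile.

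Shares with a UMI moved with depth, as thinning removes UMIs. At 500 UMIs they were 27.5% (Cd8a, WT), 0.623% and 3.18% (Cd4, WT and polyp) and 54.8% (Gzmb, WT). Without thinning they were 73.8% and 4.16% for Cd8a, 4.73% and 12.9% for Cd4, and 73.8% and 5.02% for Gzmb. Cd8a and Gzmb stayed higher in WT and Cd4 higher in the polyp at each depth.

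Among named genes, 493 comparisons with an alternative stayed within the counting interval, 82 moved and 1 reversed. For the leading lists 31 stayed, 2 moved and 4 reversed, and for the other lists 630 stayed, 52 moved and 5 reversed.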

Other observations

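The cell types of the normal library that the polyp library nearly lacked included pancreatic-acinar-like cells, 4.23% (3.56–4.99) of normal cells (134) and 0.0888% (0.0357–0.183) of polyp cells (7). Left-out barcodes showed the same contrast, with the trypsinogen gene Prss2 at 2082 CPM in WT and 144 CPM in the polyp, and Cpa1 at 813 and 25.6 CPM. The acinar-like share leaves out a cluster set apart as debris, with 1299 normal and 14 polyp barcodes, that was also closest to acinar cells by its markers. Mesothelial-like cells numbered 6 and 1.

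A Brunner-gland-like cluster was shared by the libraries (24 normal and 229 polyp cells). Its Muc6 level was close in both, 15097 and 12038 CPM, and the intestinal gene Cdx2 was present in both, 17.4 and 15.1 CPM, whereas the largely polyp cluster 14, unnamed, had Cdx2 at 1.83 and Sox2 at 26.0 CPM. Polyp crypt-like cells (19) also held Cdx2, at 78.7 CPM from 5 UMIs, against 78.4 CPM in WT. Tff1 in the shared cluster stood at 60.8 and 3882 CPM. The enteroendocrine-like cluster, in contrast, had Cdx2 at 83.4 CPM in normal and 2.53 CPM in polyp cells, and Sox2 at 0 and 20.8 CPM. The same crypt-like cells held Cd74 at 671 CPM in WT and 409 CPM in the polyp (26 UMIs), and H2-Ab1 at 121 CPM in WT and 31.5 CPM in the polyp (2 UMIs).

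Within Cd4-bearing T-like clusters of at least 50 cells (68 normal cells, cluster 11, and 817 polyp cells), chosen after the data had been seen, Cxcr4 was still 7.52-fold higher (3.19–23.3) and S100a4 2.52-fold higher (1.98–3.27) in the polyp, Gzma was at 0.143 of its normal level (0.1002–0.204), and Gzmb (1.12, 0.581–2.41) and Ifng (0.906, 0.650–1.29) had intervals across 1. The normal Gzma level in these clusters was 292 CPM from 62 UMIs, part of which can be free RNA. Il17a was at 0.617 there, against 7.44-fold higher in the whole class. The medians of the regulatory list (0.69) and of the CRTC and CREB targets (0.16) were smaller than in the whole class. With the 14 normal cells of cluster 9 included, which held 326 of the then 388 normal Gzma UMIs, Gzma was at 0.0281 (0.0216–0.0363), Gzmb at 0.242 (0.172–0.343), Foxp3 at 1.43 (0.657–3.70), Cxcr4 at 5.16 (2.68–11.4), S100a4 at 1.32 (1.12–1.57) and the regulatory list at −0.20. The same 14 cells held 47 of the then 57 normal Gzmb UMIs, and counted as Cd4-bearing on 2 Cd4 UMIs against 1 Cd8a UMI.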
